A study of Arabidopsis thaliana with 4 samples.

How the data were processed

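H3K9me2, the dimethylated form of lysine 9 of histone H3, was profiled by chromatin immunoprecipitation followed by hybridisation to a 2-colour spotted array (ChIP-chip). The material was whole Arabidopsis thaliana seedlings of the Col-0 accession, grown in liquid medium for 11 days at 22 °C under a 16 h photoperiod. Immunoprecipitated DNA (IP) was compared with input DNA of the same preparation. There were 2 preparations, here called replicate 1 and replicate 2 after the numerals I and II of the labels. Each was hybridised on 2 arrays with the Cy3 and Cy5 dyes exchanged, which makes 4 arrays in a single group. The labels do not say whether the preparations came from separate cultures, so the p-values measure only the spread between these preparations, which may be technical.

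The authors deposited 1 log-scale ratio per spotted feature and array. Per the labels' protocols, DNA was amplified and labelled directly with Cy3 and Cy5. The array platform, the background correction, the normalization, the log base, the direction of the ratio and the centring are not given in the sources used here. The base being unstated, differences are given in the deposited log units and not as folds. Of 21800 features listed, 73 were empty in all 4 columns, among them all 39 features whose identifier is not a plate and well code. The 21727 measured features had a value in every column.

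The 2 columns of a replicate, from arrays of opposite dye orientation, held identical values for every measured feature. Each replicate was therefore counted as 1 sample with 1 value per feature, and n = 2 throughout. Identical values under exchanged dyes leave the sign open, so features are described as higher or lower, not as enriched or depleted. The deposited median was -1.39 in replicate 1 and -1.15 in replicate 2, so the columns were not centred on 0. Each replicate was centred on its own median before any test. No intensities were used here, so signal over background is unknown, and the number of arrays limits the precision.

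The main test was fixed before the data were examined. It was limma's moderated test of the mean of the 2 centred replicates against 0, two-sided, with Benjamini-Hochberg adjustment over 21727 features and a threshold of 0.05 (R 4.3.3, limma 3.58.1). The moderation estimated an infinite prior degree of freedom. All features thus shared 1 standard deviation of 0.26, and the test acted as a limit of 0.42 on either side of the median. In a simulation with the observed noise and as many shifted features as the main test called, added after the data were seen, 68% of features shifted up by 0.5 units and 66.7% of those shifted down by 0.5 were recovered, and 100% (rounded) of those shifted up by 1 or 2. Of the 12913 unshifted features, 212 were called. The simulation set each of them exactly at 0, with noise of 0.2445 units per replicate. In the data the mode minus the median was -0.154 units in replicate 1 and -0.259 in replicate 2. The simulated number of false calls therefore does not carry over to the real calls. With only 50 features of each size shifted, the adjusted limit was stricter, and 24% of those shifted up by 0.5 and 96% of those shifted up by 1 were recovered. A second rule, also fixed beforehand and without a test, counted features at least 1 unit above the median in both replicates. Those features are called high-ratio features below. Alternatives were other centring, quantile normalization, other thresholds, limma's treat and a trended robust fit. A Gaussian mixture with 2 components was a further alternative (scikit-learn 1.9.0), with a posterior above 0.99 and a value above the lower component's mean required for a call. The rule for named items, in the absence of gene names, was the 2 highest and the 2 lowest called features that lay on the same side of the median in both replicates.

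The planned comparisons by chromosome region, annotation class and gene list were not run, since the features carry no position or gene name in the files used here and the RefSeq gene table could not be joined to them. In their place, features were grouped by the series, plate and well in their identifiers (PD, TA, TB, TC and TD plates of 96 wells). Wells were ordered by plate, then row, then column. The grouping, the order and the neighbour test were chosen after the data were seen. The run of at least 3 consecutive features and its alternatives had been planned for chromosome positions and were carried over to the wells. The correlation of neighbouring wells was tested by 100000 shuffles of the values within a series (one-sided). A run was a stretch of at least 3 consecutive wells called above the median, ended by any empty or unlisted well. Shares carry 95% Wilson intervals, which cover counting error only, since neighbouring features are not independent. Intervals in the closing section came from 1000 bootstrap draws of whole plates, chosen after the data were seen. Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1 were used.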

Results

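The H3K9me2 mark, a histone modification found on silent, transposon-rich chromatin in Arabidopsis, was mapped in whole seedlings as the ratio between immunoprecipitated and input DNA on a spotted array. The data comprised 4 arrays, a pair of dye-exchanged arrays for each of 2 preparations, and 21727 measured features. The paired arrays carried identical deposited values, so the analysis rests on 2 replicates. The design implies a comparison of IP with input at each feature. It also allows the preparations to be compared with each other.

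The ratios formed a large low peak and a smaller high peak, and the range between them held features without a clear peak of their own. In the mean of the replicates, 72.7% of the features (15792) lay less than 0.5 units above the median, 10.9% (2361) lay between 0.5 and 1.5 units above it, and 16.4% (3574) lay at least 1.5 units above it. These limits were chosen after the distribution was seen. The high features had a median of 2.85 units above the array median in replicate 1 and 2.35 units in replicate 2. The low features had medians of -0.13 and -0.19 units. A mixture of 3 Gaussian components described each replicate better than 2 components, with a Bayesian information criterion of 41978 against 43705 in replicate 1 and of 48070 against 49364 in replicate 2. No other numbers of components were compared, so this does not show that the intermediate features are a separate population. The uppermost of the 3 components held 15.1% of the features in replicate 1 and 15.3% in replicate 2. The middle component differed between them, with 14.0% of the features around 0.899 units in replicate 1 and 20.8% around 0.685 units in replicate 2.

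**Figure D1:**
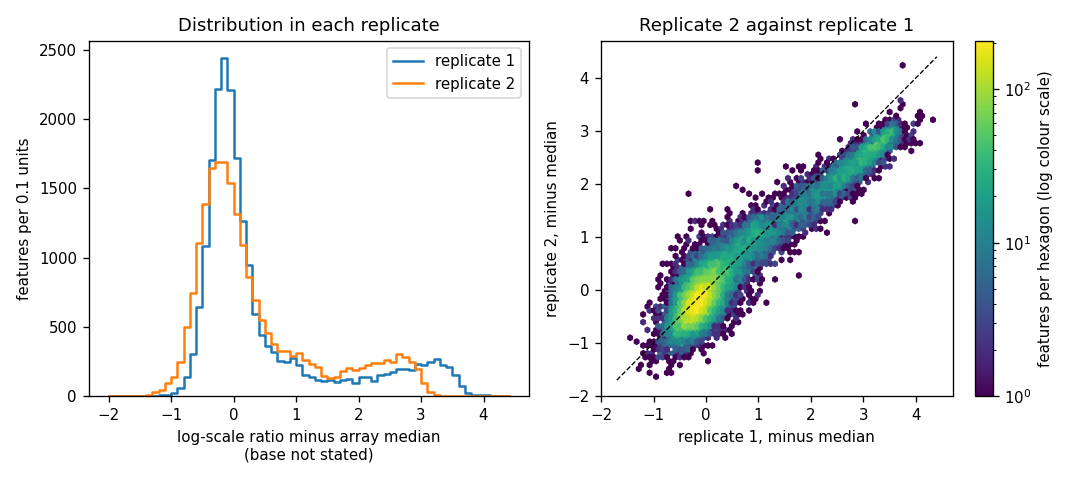
Left, number of features per bin of 0.1 units against the deposited log-scale ratio minus the array median (base not stated), for replicate 1 and replicate 2. Right, replicate 2 against replicate 1 for all 21727 features, with the colour of a hexagon giving the number of features on a log scale and the dashed line marking equal values. Both replicates show a main peak just below the median and a second, broad one at about 2 to 3.5 units, and the points of the second peak lie below the line of equal values.

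At each feature, the deposited ratio between IP and input, of unstated direction, was tested against the array median. limma called 6272 features above the median and 2542 below it at an adjusted p under 0.05 (n = 2), so that 71.2% of the calls were above. The count is relative to the median, and the calls below depended on the threshold. They numbered 1218 at an adjusted p under 0.01 and 77 with treat against 0.5. In the mean of the replicates, the lowest of 3 mixture components had a mean of -0.165 units and an SD of 0.274. The calls below, all under -0.42 units, were not told apart from the lower tail of that component. On the values as deposited, without centring, 3420 features were called above 0 and 16995 below, and 16.8% of the calls were above. Centred on the mode, which lay below the median, 7915 were called above and 738 below, and 91.5% of the calls were above. With the sign of the arrays turned, the main counts exchange places, with 2542 above and 6272 below. Under the rule of size without centring, 2220 features (10.2%) were at least 1 unit above 0 in both replicates. With centring, 4169 features (19.2%) were at least 1 unit above the median in both replicates and 15 were at least 1 unit below it in both. The asymmetry of the tails thus held in each replicate, and the deposited values had a skewness of 1.51 in replicate 1 and 1.19 in replicate 2.

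The highest feature, TB40E11, lay 3.98 ± 0.36 units (SD, n = 2) above the median, with an adjusted p of 1.86e-101 in limma. Its neighbours in well order lay at -0.25 and 0.21 units, so this was a single high feature between low ones. The next, TA21E04, lay 3.75 ± 0.82 units above the median (adjusted p of 7.78e-90 in limma), between neighbours at 2.93 and 3.67 units. The lowest features were TB81A05, at -1.41 ± 0.18 units, with an adjusted p of 5e-14 in limma, and TB34E02, at -1.34 ± 0.34 units, with an adjusted p of 8.26e-13. The neighbours of TB81A05 lay at -0.42 and -0.61 units. Those of TB34E02 lay at -0.19 and -1.24 units. These p-values follow from a spread shared by all features and are small because that spread is 0.26 units.

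Across all features, Pearson's r between the replicates was 0.953 and Spearman's rho 0.817, values taken across features, which are not independent replicates. Since the ratios form a low and a high peak, the correlation was also taken within the low, intermediate and high features. Pearson's r was 0.538 among the low features, 0.447 among the intermediate features and 0.907 among the high features. Among the 2542 features called below the median, Pearson's r was 0.012 and Spearman's rho -0.116. All these groups were selected on the mean of the same 2 replicates, which by itself lowers the correlation, most of all in a narrow range, so these values do not rank the agreement of the groups. The difference between the replicates had an SD of 0.317 units among the low, 0.336 among the intermediate and 0.244 among the high features, and of 0.272 units among those called below. Over all features it was 0.346 units, against 2.98 units between the low and high medians of replicate 1 and 2.54 units in replicate 2. Replicate 2 separated the low and high features by 0.852 times the distance in replicate 1. It nevertheless spread the low features more widely, with an SD of 0.364 units against 0.275. The median difference, replicate 2 minus replicate 1, was -0.481 units among the high features and 0.049 units among the intermediate features.

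High-ratio features were unevenly shared among the plate series. They made up 29.2% of the TA features (2728 of 9330, 95% Wilson interval 28.3 to 30.2), 3.5% of the TB features (332 of 9591, 3.1 to 3.8) and 45.2% of the TC features (1081 of 2394, 43.2 to 47.2). The share was 4.1% in the 4 PD plates (2.4 to 6.9) and 15.6% in the single TD plate (9.7 to 24.2). The gap between TA and TB plates was 25.8 percentage points and was present in each replicate, with 31% against 4.4% in replicate 1 and 31.8% against 4.9% in replicate 2. Without centring the gap was 13.5 points. limma called below the median 9.0% of the features in TA, 15.4% in TB, 8.8% in TC, 1.9% in PD and 0.0% in TD plates, so a low share of high-ratio features did not always go with many calls below. The series differ in which features they hold, so these shares carry no test of a condition.

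Within the series, high-ratio features were gathered in blocks of neighbouring plates. Of 231 plates, 41 had more than 50% high-ratio features, 28 of them in the TA series and 13 in the TC series. These 41 plates held 71.6% of all high-ratio features. The blocks described next were delimited after the plate values were seen, so no test is given between them. From TA01 to TA20, 7.2% of the features were high-ratio features (single plates 0.0% to 34.4%). From TA21 to TA30 the share was 66.4% (55.8% to 93.3%). It was 19.6% from TA31 to TA36 (2.1% to 44.8%), 87.0% from TA37 to TA51 (62.5% to 100%) and 30.8% from TA52 to TA66 (8.3% to 61.5%). From TA67 to TA99 it was 8.6% (0.0% to 51%). The highest plate of this last block was TA95, at 51%. These shares are of measured features, and not every plate had 96 of them. In the high blocks, TA22 had 60, TA38 had 62 and TA39 had 42, although most plates from TA37 to TA51 had 96. Each plate from TA31 to TA36 and from TA52 to TA66 had 96. Whether missing wells go with high ratios was not tested.

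**Figure D2:**
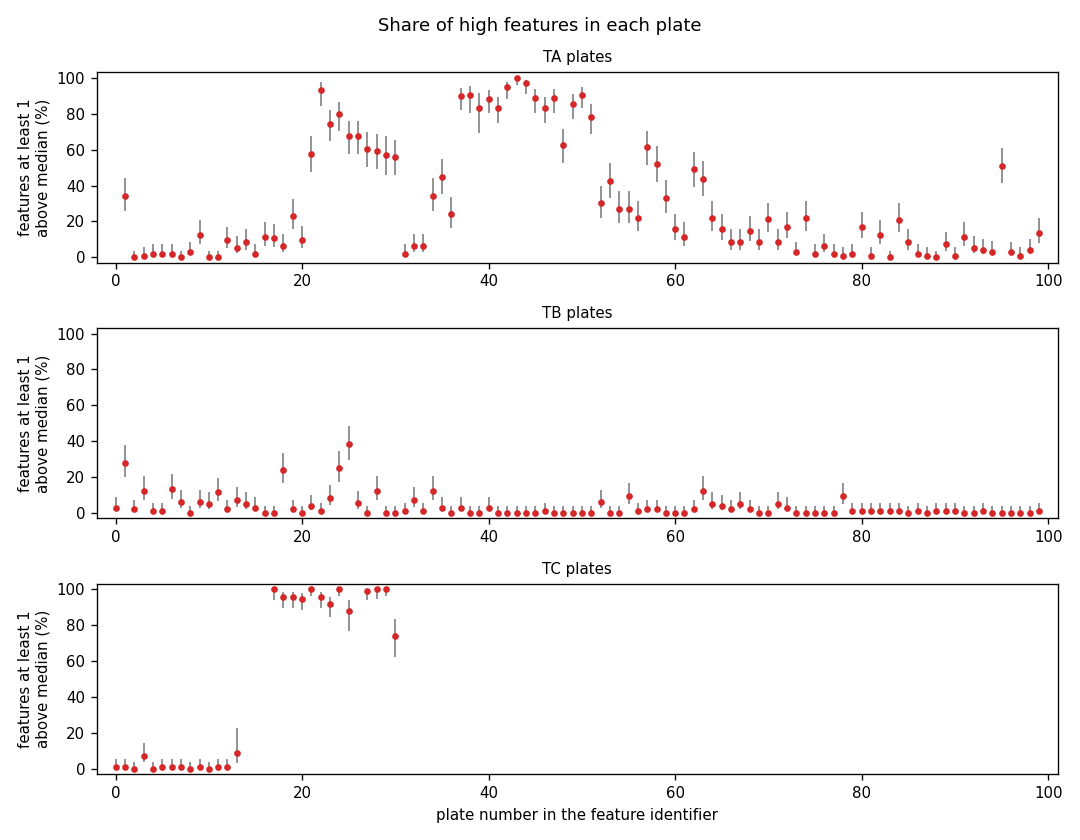
Percent of features at least 1 unit above the median in both replicates (points) against the plate number in the identifier, for the TA, TB and TC series, with vertical bars for 95% Wilson intervals (counting error only). High shares occupy TA21 to TA30, TA37 to TA51 and TC17 to TC30, while the TB plates stay at or below 38.5%.

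The TC series split into 2 parts. No measured feature carried a plate number between TC13 and TC17, so the change from one part to the other was not observed. In TC00 to TC13, 1.4% of the features were high-ratio features (single plates 0.0% to 8.8%) and the median of the mean ratio was -0.17 units. In TC17 to TC30, 95.6% were high-ratio features (74.2% to 100%) and the median was 2.77 units. The replicates gave the same order, with medians of 3.03 and 2.49 units in the upper part and of -0.14 and -0.19 units in the lower part. In the TB series, TB25 had the largest share, 38.5% (29.4 to 48.5). That share depended on the replicate and the threshold. In TB25, 57.3% of the features were at least 1 unit above the median in replicate 1 and 38.5% in replicate 2. The median of its mean ratio was 0.97 units, and 13.5% had a mean of at least 1.5 units. The share of high-ratio features was 6.9% in TB00 to TB24 and 1.8% in TB26 to TB99.

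Neighbouring wells carried similar ratios in every series. The Pearson correlation between a well and the next was 0.884 in TA, 0.615 in TB, 0.962 in TC, 0.62 in PD and 0.618 in TD plates. The permutation p was 1e-05 in each of the 5 series, the smallest that 100000 shuffles can give, and 1e-05 after Benjamini-Hochberg adjustment. For this test each feature was paired with the next measured one, also across empty or unlisted wells. The correlations above use directly consecutive wells only, with 9248 pairs among the 9330 TA features. Shuffling over a whole series also breaks up the plate blocks described above. The p therefore does not separate likeness of adjacent wells from these blocks. The highest correlation among the shuffles was 0.041 in TA, 0.045 in TB, 0.083 in TC, 0.277 in PD and 0.445 in TD plates. Each replicate showed it alone, with 0.888 and 0.859 in TA plates. A well and the one below it in the same plate column correlated at 0.562 in TA, 0.147 in TB, 0.893 in TC, 0.086 in PD and 0.401 in TD plates. Each value was below that for the next well, by the smallest margin in TC plates.

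The features called above the median formed 362 runs of at least 3 consecutive wells, which held 4936 of the 6272 called features (78.7%). Shuffling the calls within each series, 100 times, gave 578.3 runs on average, but these were short, held 35.0% of the calls and never exceeded 20 wells. This shuffling also breaks up the plate blocks, so 20 wells is no limit for runs inside a block. limma called above the median 98.7% of the features in TC17 to TC30 and 94.7% in TA37 to TA51. At such a density long runs can arise without further likeness of adjacent wells, and the 5 longest runs all lay in these blocks. The observed runs reached 251 wells, and 16 had 50 wells or more. The longest had 501 wells where single uncalled wells, in any number, were allowed inside a run. It had 150 wells under the mixture call and under the rule of size. The 5 longest ran from TC22D03 to TC25A01 (251 wells), TC18H11 to TC21C07 (225 wells), TA44B08 to TA45H05 and TC27A01 to TC28F10 (166 wells each), and TA42E04 to TA44B06 (159 wells). Their mean ratios were 2.46, 2.55, 2.39, 2.74 and 2.65 units above the median.

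**Figure D3:**
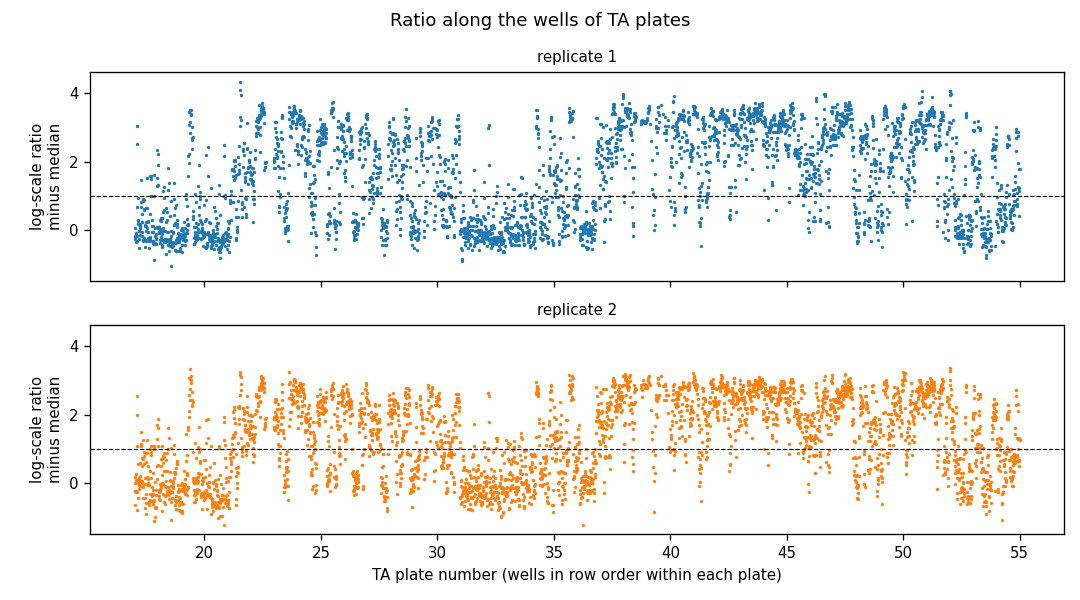
Log-scale ratio minus the array median (base not stated) of each TA feature from plate TA17 to TA54, in well order, for replicate 1 (top) and replicate 2 (bottom), with the dashed line at 1 unit. Both replicates rise and fall together along the wells, and low features also occur inside the high blocks.

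Outside TA21 to TA30, TA37 to TA51 and TC17 to TC30 lay 1343 high-ratio features. They formed 137 runs of at least 3 wells, and 279 stood alone. The longest of these runs were TA56H01 to TA57B04 with 28 wells at a mean of 2.08 units, TA63A04 to TA63C02 with 23 wells at 2.53 units and TA01A01 to TA01B09 with 21 wells at 2.09 units. In TB plates, 196 of the 332 high-ratio features (59.0%) lay in runs of at least 3 wells, and 90 (27.1%) had no high-ratio feature beside them. The share standing alone was 7.8% in TA, 2.7% in TC, 23.1% in PD and 40.0% in TD plates. It depends on how dense high-ratio features are: shuffled within their series, 100 times, 93.4% stood alone on average in TB, 50.4% in TA, 30.5% in TC, 92.8% in PD and 71.9% in TD plates. The observed share lay below every shuffle in all series but TD, where the lowest shuffle gave 40.0% as well. These shuffles ran over whole series and so broke up the plate blocks. In TC plates they mixed a part with 1.4% and a part with 95.6% high-ratio features. The comparison therefore does not separate grouping of adjacent wells from the plate blocks. The TB series held 35 runs of at least 3 wells, the longest being TB18G03 to TB18H08 with 18 wells at a mean of 2.28 units, followed by TB01D10 to TB01E08 with 11 wells at 2.47 units. These runs were chosen by length after the values were seen.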

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

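Without centring, limma called 3420 features above and 16995 below, and 2220 were at least 1 unit above 0 in both replicates; the gap between TA and TB plates was then 13.5 percentage points. Calls below the median fell to 738 with centring on the mode, to 1218 at an adjusted p under 0.01 and to 77 with treat against 0.5. Turning the sign gave 2542 calls above, 6272 below and 15 features past the rule of size. The other counts above the median (4440 to 7915) stayed within 1.5 times the main count. Runs numbered 217 with at least 5 wells and 364 with single uncalled wells allowed in any number. The longest had 501 wells with single uncalled wells allowed and 150 by mixture or by size. Pearson's r was 0.512 among features not called above, a narrower range of ratios. The gap between TA and TB plates was 33.1 points by the limma call. Leaving out a replicate gave 26.6 to 26.9 points, and 4442 to 4582 features past the rule of size. The settings on runs of wells, on TA against TB and on turned signs of the size rule were chosen after the data were seen. Leaving out a replicate leaves no test. Single dye orientations hold the same values, and a filter for features measured on all arrays removed none. Fits of 4 arrays with a random block or a dye term, the dye effect and a tested difference between replicates were not run, because the paired columns are identical. Comparisons by region, annotation, GC content and gene list were not run for want of positions.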

Other observations

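The tests on the intermediate features, on plate borders and on saturation were set before their results were seen; those on compression and on chromosome order were chosen only after the plate and replicate values had been seen. The intermediate features made up 26% of the features in the single TD plate, 16.2% in TA, 14.2% in PD, 6.8% in TB and 5.6% in TC plates. They made up 25.8% of the features from TA52 to TA66 and 44.8% of plate TB25, against 4.8% from TB26 to TB99. Among the 5 longest runs of high-ratio features, the wells from TC29A01 to TC30B01 stood apart by their evenness. Their 109 features had a mean of 3.09 units with an SD of 0.13 over features, while the other 4 had SDs of 0.37 to 0.47. Within that run the replicates correlated at 0.49, against 0.9 to 0.96 in the other 4. So narrow a range by itself lowers the correlation, so it is not a further difference.

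High features lay next to each other in well order. If each plate had its own level, wells on either side of a plate border would differ as much as any wells of those plates. Across 216 borders they differed by 0.391 units on average, against 0.648 units for random wells of the same 2 plates, a ratio of 0.603 (permutation p of 1e-05, the smallest that can be given), and the next well within a plate differed by 0.337 units. This argues against a separate level for each plate as the whole source of the blocks. A gradient over the printing order, or a batch of several plates, would also leave border wells alike, so neither was tested by it. A candidate explanation is that the wells follow the order of tiles along a chromosome, with the high blocks in heterochromatin, in which case IP over input is the likely direction. The chromosome is not named in the sources used here. Taking it as chromosome 4 with evenly spaced tiles from the first TA well, the window named for the heterochromatic knob (1.6 to 2.3 Mb) held 65.0% high-ratio features and its flanks (0 to 1.6 and 2.3 to 2.8 Mb) 11.9%, a difference of 53.0 percentage points at a spacing of 0.85 kb (p of 0.02 over all 9330 rotations). At that spacing the flanks end in plate TA35, so the larger block from TA37 to TA51 took no part in the comparison. The window limits were fixed before the data were examined, but the placing of TA wells along the chromosome, the starting well, the spacing and the test were chosen after the plate values had been seen, so this p is not independent evidence. The difference was 13.7 points at 0.7 kb (p of 0.47) and 25.9 points at 1.0 kb (p of 0.226), and 3 of the 5 spacings passed, so without tile positions the order stays open.

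Replicate 1 separated the low and high features more widely than replicate 2. A single compression factor would shrink the spread of low features as well. The SD ratio of replicate 2 over replicate 1 among low features exceeded the ratio of the separations by 0.471 (95% interval 0.441 to 0.499, from resampling whole plates, which leaves out the spread between preparations), which argues against it as the whole difference. Saturation of the brightest features in replicate 2 would narrow the high features further. Their SD ratio differed from the ratio of the separations by -0.027 (-0.055 to 0.001), less than the 0.1 set beforehand. That SD covers all high features, and added noise in replicate 2 could mask a narrowing, so this test cannot exclude saturation. The medians of the intermediate features were close, at 0.89 and 0.93 units in replicates 1 and 2. Those of the high features were 2.85 and 2.35 units. Both groups were cut on the mean of the 2 replicates, and replicate 2 spread the low features more widely (SD 0.364 against 0.275 units). The close medians of the intermediate features therefore do not show that the replicates differ only at the upper end. Saturation stays open, as does more noise in replicate 2 together with a lower yield of the immunoprecipitation, and no biological explanation was tested.

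The intermediate features recurred in both replicates. Of the features intermediate in replicate 1, 81.1% were intermediate in replicate 2 (78.6 to 83.3, resampling plates), which argues against noise between the replicates as their main source. If they were the edges of high blocks, most would touch a high feature. Of them 22.1% did (18.8 to 25.5), against 1.3% of low features. This lies below the 50% set for edges as the main source, but its interval reaches the 25% set for excluding them, so edges may account for part of the group. With any neighbour at or above 0.5 units counted, the share was 68.0%. The same share among low features was not computed, so this value has no baseline. Features that hybridise to several copies in the genome, or partial occupancy across the cells of a whole seedling, were not tested here.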
